A study of Mus musculus with 4 samples.

How the data were processed

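Total RNA of MACS-sorted CD24+ liver cells was extracted with a column kit and made into paired-end stranded mRNA libraries, per the labels' protocols. The series holds 4 libraries, 2 of HACY and 2 of CCL4 mice, and groups and replicate numbers came from the sample titles. Each library has a deposited table with a count and an FPKM per gene symbol. The count column holds raw read counts per gene, per the file headers, whole numbers that sum to 18467299 to 19314219. The FPKM column was made by the authors, per the file headers, and is scaled to transcript length and library size. Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq are named, and the build mm10, per the submitters' processing notes, with no versions or roles. The annotation and the strand setting of the counting are not given in the sources used here, so genes that overlap on opposite strands are uncertain, as are genes with near-identical copies.

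The tables hold 21878 rows, of which 20639 match a symbol of the GENCODE annotation of GRCm38 (the same assembly as mm10) used for locations. There were 27 rows with names turned into dates by a spreadsheet. They hold at most 0.2% of a library's counts and were tested but never named. No row carried a mitochondrial prefix or an immunoglobulin chain name, and 8 were haemoglobin genes. Before averaging, replicates were compared: chi-square per degree of freedom was 19.8 between the HACY libraries and 35.6 between the CCL4 libraries, so no library is a copy of another. A count of 0 allows up to 3 counts, or 0.155 to 0.162 CPM, and covers counting error only.

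Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and fitted by the robust quasi-likelihood method with treatment as the only term. The test was two-sided, with Benjamini-Hochberg adjustment over 13428 genes and a threshold of 0.05. The common dispersion was 0.0272, a biological coefficient of variation of 16.5%. Log2 fold changes are HACY over CCL4, CPM (counts scaled to library size by edgeR) are TMM-scaled, and standard errors are the log2 fold change divided by the square root of the F statistic, an approximation. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 35 lists with at least 5 tested members, with an estimated correlation and fry as alternatives. Shares of counts were compared by exact permutation with SciPy 1.17.1.

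The 37 lists, the tests, the rule for named genes and the other settings, apart from those named below as added, were fixed before the data were examined. The rule names Cd24a, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap (predicted genes and pseudogenes passed over), and up to 4 members per list with the smallest p. Other genes are named as chosen after their values were seen, and some genes that were tested are not reported here. On simulated counts with 200 changed genes (13301 genes), the HACY against CCL4 test recovered 12.2% of changes of 1.5-fold, 48.0% of 2-fold, 91.8% of 4-fold and 100% of 8-fold, with 3 false calls among 128. The simulated shifted list was called and 0 of 36 unchanged lists were. Simulated genes were drawn independently, whereas the median estimated correlation within the real lists was 0.18. The simulation therefore gives no error rate for lists of correlated genes.

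Alternatives were RLE, upper-quartile and library size scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, a fold threshold, a block on replicate number, removal of haemoglobin genes and each library left out. After seeing the data, limma on log2(FPKM + 1), offsets for GC content and length (natural splines, for 96.6% of tested genes) and list counts and compared medians without each library were added.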

Results

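RNA was sequenced from liver cells of C57BL/6 mice that had been sorted on magnetic columns (MACS) for the surface protein CD24, a marker used to collect liver progenitor cells. CD24 is also carried by neutrophils, B cells and red cell precursors. The labels describe the cells as hepatocytes. There were 2 groups of 2 libraries, and no untreated or vehicle group. Rises and falls below are therefore HACY relative to CCL4, and none can be assigned to either treatment alone. Mice of both groups were 8 weeks old when injected. CCL4 mice received carbon tetrachloride, a hepatotoxin, at 2 ml/kg in olive oil, 2 times a week for 6 weeks. HACY mice received a cocktail of Y-27632, a kinase inhibitor, A-83-01, an inhibitor of TGF-beta type I receptor kinases, and CHIR99021, an inhibitor of glycogen synthase kinase 3, with injections 3 times a week for 6 weeks. Whether the HACY mice were also given carbon tetrachloride is not clear from the labels. The count tables summed to 19151738 and 18985478 for HACY replicates 1 and 2, and to 18467299 and 19314219 for CCL4 replicates 1 and 2. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No batch is given in the labels.

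The comparison asked how CD24+ cells of the 2 treatments differ in expression. In these bulk libraries a change in the mix of cells cannot be told apart from a change within cells. HACY libraries held more RNA of hepatocyte products, cytochromes P450, acute phase and complement proteins, macrophage markers and interferon response genes. They held less of several hepatocyte transcription factors and p53 targets. These lists were called by camera with its preset correlation. None of 35 lists was called with an estimated correlation (smallest adjusted p = 0.415) or by fry (0.0569). With an estimated correlation camera rests on the few residual degrees of freedom of 4 libraries, so a lost call need not be due to correlation between genes. Of 13428 genes tested, 1576 differed at an edgeR adjusted p below 0.05, with 1100 higher and 476 lower in HACY. A further requirement of a 2-fold change left 696 higher and 232 lower. Groups did not overlap for 60.8% of the tested genes, against 33.3% by chance. Pearson's r across genes, which are not independent replicates, was 0.988 between the HACY libraries, 0.978 between the CCL4 libraries and 0.945 to 0.959 between groups. The leading principal component held 70.5% of the variance and separated the groups, and the next held 19.4% and separated the CCL4 replicates. The number of calls was 629 without HACY replicate 1, 780 without HACY replicate 2 and 3047 without CCL4 replicate 2. The split depended on scaling. By library size alone, 856 genes were higher and 1355 lower, with the median of all genes at -0.18 instead of -0.01 on the log2 scale. The deposited FPKM gave 670 higher and 664 lower, but there the test (limma), the scale and the genes tested (11179) differed as well.

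Cd24a, the gene of the sorted protein (chromosome 10, 43578284 to 43584265, GRCm38), had 20.6 ± 1.80 CPM, counts scaled to library size, in HACY and 29.3 ± 12.2 in CCL4 (SD, n = 2). Its log2 fold change was -0.51 (SE 0.29, edgeR adjusted p = 0.279). Without CCL4 replicate 1 the value was -0.88 (adjusted p = 0.0290), and without CCL4 replicate 2 it was -0.0033 (0.990). The 20 most abundant genes took 10.5% ± 1.04 of the counts in HACY and 8.14% ± 0.508 in CCL4, and ribosomal protein genes took 2.81% ± 0.0213 and 3.80% ± 0.110 (SD, n = 2). Haemoglobin genes took 0.000391% ± 7.29e-05 and 0.000171% ± 8.07e-05. Each of these differences had an exact two-sided permutation p = 0.333, the smallest that 2 against 2 libraries can give.

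The largest rises were in genes of diverse tissues. Ivl, which encodes involucrin, a precursor of the cornified envelope of skin (chromosome 3, 92570902 to 92573735), rose from 11.7 ± 4.17 to 211 ± 27.8 CPM (SD, n = 2), 17.9-fold (log2 4.16, SE 0.25, edgeR adjusted p = 9.25e-04). Prg4, the gene of lubricin (chromosome 1, 150449412 to 150466165), rose from 20.5 ± 1.04 to 293 ± 75.1 CPM. Liver-secreted proteins among them were Serpina6, corticosteroid-binding globulin (log2 4.06), and Serpina1e, of the alpha-1-antitrypsin family (3.66). Others were Gstm3, a glutathione transferase (4.13), Ms4a4c, a membrane protein gene (4.03), Edn1, which encodes endothelin (3.87), Npy, neuropeptide Y (3.35), and Cyp1a2, a xenobiotic oxidase (3.34). Serpina1e, Gstm3 and Ms4a4c have near-identical relatives, so their counts are uncertain. The call of Serpina1e was lost without CCL4 replicate 1 or CCL4 replicate 2 (adjusted p = 0.0782 and 0.0777), and that of Cyp1a2 without HACY replicate 1 or HACY replicate 2 (0.0625 and 0.0530).

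Among the falls, Scnn1a, a subunit of the epithelial sodium channel (chromosome 6, 125320659 to 125344943), had 7.27 ± 0.158 CPM in HACY (SD, n = 2), 6.87-fold lower than in CCL4, where the libraries had 60.7 and 39.2 (log2 -2.78, SE 0.25, edgeR adjusted p = 0.00179). Ppargc1a, a coactivator of mitochondrial genes, had a log2 fold change of -2.62, Car6, a secreted carbonic anhydrase, -2.76, Adora1, an adenosine receptor, -2.21, and C77370 -2.80. Slc6a19, a neutral amino acid transporter, had -3.47, Dtx1, a NOTCH regulator, -2.48, Il1f9, an interleukin, -2.42, and Cyp27b1, which activates vitamin D, -2.23. Mmp9, a gelatinase abundant in neutrophils, had -2.62, with 18.5 CPM in CCL4 replicate 1 and 89.5 in CCL4 replicate 2. Calls of Slc6a19, Il1f9 and Mmp9 were lost without either HACY library (adjusted p = 0.161 and 0.136, 0.0943 and 0.107, and 0.698 and 0.660), and that of Cyp27b1 without HACY replicate 2 (0.116) or CCL4 replicate 1 (0.103). Without CCL4 replicate 2 the value of Mmp9 was -1.07 and that of Il1f9 -1.47, and DESeq2, limma-voom, FPKM and the GC content and length correction ended the Mmp9 call.

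**Figure D1:**
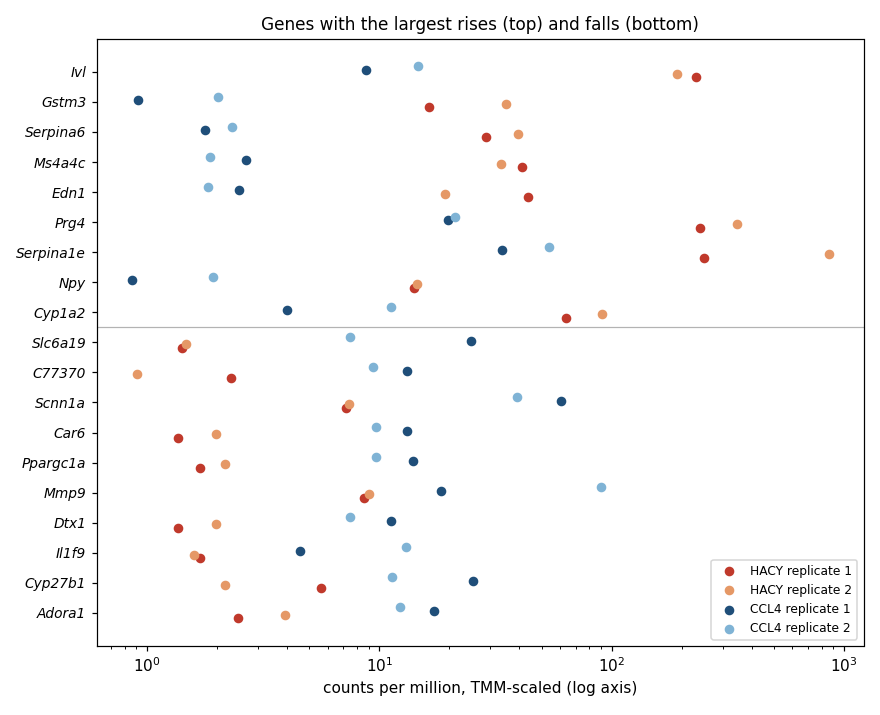
TMM-scaled CPM (log axis) of 9 of the genes with the largest rises and the 10 with the largest falls, with a point for each of the 4 libraries. Both HACY points lie on the same side of both CCL4 points for each gene; Ivl has 191 and 230 CPM in HACY against 8.80 and 14.7 in CCL4.

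Secreted hepatocyte proteins were higher in HACY. Of 19 tested members 13 rose and none fell (17 rose when adjusted over the list alone), with a median log2 fold change of 1.30. Fga and Fgb, fibrinogen chains, rose by 2.49 (SE 0.13) and 2.11 (SE 0.12), and Ahsg, fetuin-A, by 2.27 (SE 0.16). Alb, albumin, chosen after its values were seen, took 2.56% ± 0.369 of the counts in HACY and 0.662% ± 0.120 in CCL4 (SD, n = 2). The list was higher by camera (adjusted p = 5.25e-11; adjusted p = 0.415 with an estimated correlation). Xenobiotic cytochromes P450 had 12 of 16 members higher and none lower (15 higher when adjusted over the list alone), with a median of 2.02. Cyp2c29 went from 22.7 ± 3.86 to 204 ± 49.5 CPM and Cyp3a11 from 52.0 ± 14.0 to 293 ± 73.2 (SD, n = 2). Camera gave adjusted p = 1.85e-09 (adjusted p = 0.415 with an estimated correlation). Counts of the Cyp2c, Cyp2d, Cyp3a and Serpina1 families are uncertain between paralogs.

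Urea cycle and amino acid catabolism genes included 6 rises and 1 fall among 15 tested (also 6 and 1 when adjusted over the list alone; median 0.59). Otc, which makes citrulline in the urea cycle, rose by 2.43 (SE 0.23) and Hpd, of tyrosine breakdown, by 1.47 (SE 0.14). Nags, which makes the activator of the cycle's entry enzyme, had -1.17 (SE 0.21), a call lost without HACY replicate 1 (adjusted p = 0.101). Camera gave adjusted p = 0.0167 for the list (adjusted p = 0.506 with an estimated correlation). In the bile acid list 4 of 15 rose and 1 fell (5 and 1 when adjusted over the list alone; median 0.01; camera adjusted p = 0.302, and 0.0191 without HACY replicate 1, where the median was 0.32). The bile acid median was -0.14 without HACY replicate 2, 0.21 without CCL4 replicate 1 and 0.13 without CCL4 replicate 2. Slc10a1, the bile acid uptake carrier of hepatocytes, rose by 2.62 (SE 0.36) and Slc27a5 by 1.86 (SE 0.26), while Abcc2, an export pump, had -0.54 (SE 0.13), a call lost without HACY replicate 1, HACY replicate 2 or CCL4 replicate 1 (adjusted p = 0.260, 0.171 and 0.0728).

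Zonal genes of the liver included rises in both zones, but the zonal lists share members with lists above. The periportal list shares Hal, Sds, Gls2, Arg1, Cps1 and Ass1 with the urea cycle list and Cyp2f2 with the cytochrome P450 list. The pericentral list shares Cyp2e1 and Cyp1a2 with the cytochrome P450 list. Of 14 periportal genes 6 rose and none fell (7 rose and 1 fell when adjusted over the list alone; median 0.62), among them Hsd17b13, a lipid droplet protein (2.80, SE 0.30), and Cyp2f2 (1.91, SE 0.22). Camera gave adjusted p = 0.0114 (adjusted p = 0.588 with an estimated correlation). Of 13 pericentral genes 4 rose and none fell (5 rose when adjusted over the list alone; median 0.50), including Lect2 (1.65, SE 0.25), at a camera adjusted p = 0.0261 (adjusted p = 0.415 with an estimated correlation). Without CCL4 replicate 1 the pericentral call was lost, and 2 members rose without HACY replicate 1 or HACY replicate 2. Metabolic lists held few calls: Scd1, a fatty acid desaturase, rose among 20 lipid synthesis genes (1.20, SE 0.20), Cyp4a10 among 19 fatty acid oxidation genes (1.34, SE 0.32) and Fbp1, of gluconeogenesis, among 19 glycolysis and gluconeogenesis genes (1.63, SE 0.21). No member fell in the main test, but 2 oxidation and 2 synthesis genes fell by library size alone, and 1 of each after correction for GC content and length. Adjusted over the list alone the counts were 1, 0 and 1, and camera adjusted p = 0.842, 0.279 and 0.290. The Cyp4a10 call was lost without HACY replicate 2 (adjusted p = 0.213) or CCL4 replicate 2 (0.0594), and 2 oxidation genes rose without CCL4 replicate 1 or CCL4 replicate 2. For glycolysis, 2 rose without HACY replicate 1 and 3 without CCL4 replicate 2, and the list passed camera's threshold without HACY replicate 1 (adjusted p = 0.00397). The Scd1 call was lost without CCL4 replicate 1 (0.0502), and 1 oxidation and 1 synthesis gene fell without CCL4 replicate 2.

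**Figure D2:**
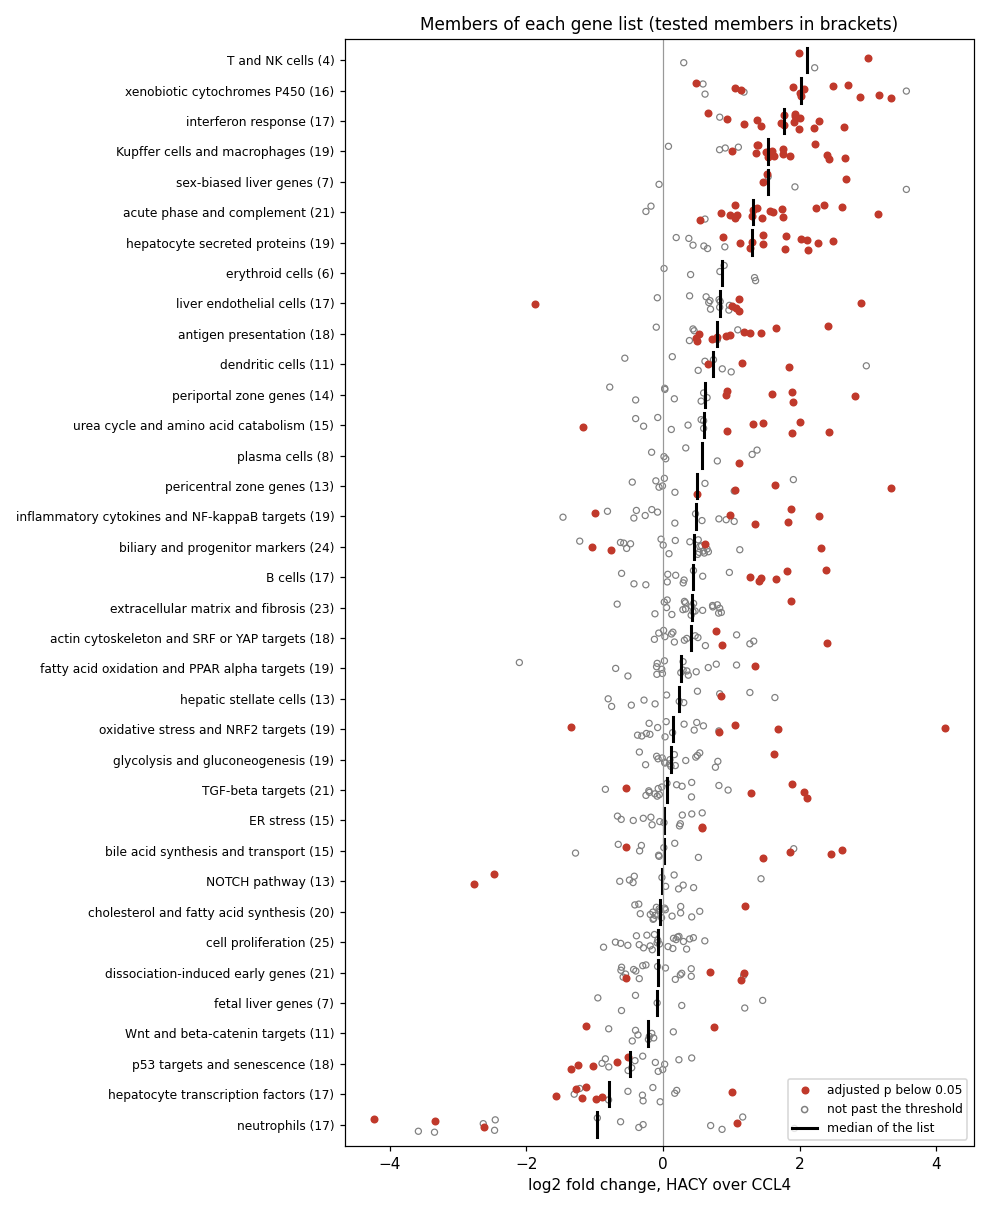
Log2 fold change (HACY over CCL4) of each tested member of 36 gene lists, filled where the edgeR adjusted p is below 0.05, with the list median as a black bar. Medians run from -0.96 for neutrophil markers to 2.02 for cytochromes P450, apart from the 4 tested T and NK cell genes at 2.11.

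Hepatocyte transcription factors went the other way from hepatocyte products. Of 17 tested, 6 fell and 1 rose (8 and 1 when adjusted over the list alone), with a median of -0.80. Prox1 had -1.28 (SE 0.19, edgeR adjusted p = 0.00898) and Cebpa -0.90 (SE 0.15, adjusted p = 0.0130). Nr1h3, the oxysterol receptor LXR alpha, rose by 1.01 (SE 0.15). Hnf4a, chosen after its values were seen, had 110 CPM in HACY and 114 in CCL4. Camera gave adjusted p = 0.00145 for the list (adjusted p = 0.415 with an estimated correlation). The number of falls was 2 without HACY replicate 1 and 3 without HACY replicate 2. The Nr1h3 call was lost without HACY replicate 1 (adjusted p = 0.0555) and that of Cebpa without HACY replicate 2, where its value was -0.77.

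Biliary and progenitor markers were not called as a group. Of 24 tested, 2 rose and 2 fell (4 and 2 when adjusted over the list alone; median 0.45; camera adjusted p = 0.503). Anxa4 had 0.61 (SE 0.12), Cftr, the chloride channel, 2.31 (SE 0.51), Prom1, a progenitor surface protein, -1.04 (SE 0.19) and Sox4 -0.75 (SE 0.17). Each of these calls was lost without HACY replicate 1 (adjusted p = 0.180, 0.260, 0.139 and 0.0909), those of Anxa4 and Sox4 also without HACY replicate 2 (0.109 and 0.108) and that of Cftr without CCL4 replicate 1 (0.0583), and by library size alone Anxa4 was lost (0.0577). The counts were 8 and 2 without CCL4 replicate 2, 2 and 0 without HACY replicate 1, where other members rose, 1 and 1 without HACY replicate 2 and 1 and 2 without CCL4 replicate 1, and the median was 0.29 without HACY replicate 1, 0.25 without HACY replicate 2 and 0.013 without CCL4 replicate 1. None of 7 fetal liver genes passed edgeR's threshold or DESeq2's, and 1 had a positive and 3 a negative change at an unadjusted p below 0.05. There was 1 rise and 1 fall without CCL4 replicate 2, where Cdkn1c, a cell cycle inhibitor, had 1.67 (adjusted p = 0.0482), and also after correction for GC content and length, and 1 fall by library size alone. None passed when adjusted over the list alone (camera adjusted p = 0.842), and Afp, alpha-fetoprotein, had -0.61 (SE 0.23). Among 13 NOTCH genes Jag2, a ligand, had -2.77 (SE 0.51) and Dtx1 fell, and none rose (1 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.715). Without HACY replicate 1 there was 1 fall, Jag2 being lost (adjusted p = 0.108), and without CCL4 replicate 2 there was 1 rise.

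For the pathways that the cocktail's molecules act on, the lists gave the following. Of 11 Wnt and beta-catenin targets Cd44, a hyaluronan receptor, rose by 0.74 (SE 0.14) and Tbx3 had -1.12 (SE 0.28; 1 rise and 2 falls when adjusted over the list alone; median -0.21; camera adjusted p = 0.0940). Axin2, a feedback target, had -0.45 (SE 0.27, adjusted p = 0.317). The Cd44 call was lost without HACY replicate 2 (adjusted p = 0.117) or CCL4 replicate 1 (0.0537), the Tbx3 call without HACY replicate 1 (0.125), HACY replicate 2 (0.297) or CCL4 replicate 1 (0.0803), and the list passed camera's threshold without HACY replicate 1 (0.0189, median -0.50) or without CCL4 replicate 1 (0.0413, median -0.34). Of 21 TGF-beta targets 4 rose and 1 fell (5 and 1 when adjusted over the list alone; median 0.06; camera adjusted p = 0.218). The rises included Tgfbi (2.06, SE 0.27), the integrin gene Itgb6 (1.89, SE 0.22) and Ltbp2 (1.29, SE 0.23), and the fall was Junb (-0.54, SE 0.14). Ltbp2 was named after its values were seen. Without CCL4 replicate 2 there were 7 rises and 2 falls, the median was 0.13 without HACY replicate 1, and the Junb call was lost without HACY replicate 1 or HACY replicate 2 (adjusted p = 0.237 and 0.205) and after correction for GC content and length (-0.17, 0.291).

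Actin cytoskeleton genes and targets of SRF or YAP had 3 rises and no fall among 18 (9 rises when adjusted over the list alone; median 0.41; camera adjusted p = 0.00375; adjusted p = 0.588 with an estimated correlation). These were Tagln (2.40, SE 0.43), Actg1 (0.87, SE 0.17) and Axl, a receptor kinase chosen after its values were seen (0.77). Extracellular matrix genes had 1 rise among 23, Postn, periostin (1.87, SE 0.36), and 1 when adjusted over the list alone (median 0.42; camera adjusted p = 0.0125; adjusted p = 0.775 with an estimated correlation). CCL4 replicate 2 held more matrix RNA than CCL4 replicate 1, by a median of 1.10 on the log2 scale. Without CCL4 replicate 2, 10 actin and 16 matrix genes rose (medians 0.65 and 1.07), and without CCL4 replicate 1 the matrix call was lost, with a median of 0.039, 1 rise and 1 fall. The Actg1 call was lost without HACY replicate 2 (adjusted p = 0.0546) or CCL4 replicate 1 (0.0526).

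Interferon response genes rose in near unison. Of 17 tested, 16 rose (17 when adjusted over the list alone), with a median of 1.77. Ifit3, an antiviral effector, went from 37.7 ± 5.34 to 237 ± 52.6 CPM, Irf7, a transcription factor of the response, from 207 ± 2.48 to 706 ± 83.4, and Zbp1, a nucleic acid sensor, from 74.9 ± 7.53 to 286 ± 22.1 (SD, n = 2). Camera gave adjusted p = 3.09e-12 (adjusted p = 0.415 with an estimated correlation). Antigen presentation genes had 12 rises and no fall among 18 (15 rises when adjusted over the list alone; median 0.79; camera adjusted p = 4.34e-08; adjusted p = 0.415 with an estimated correlation). Ctss, a lysosomal protease, rose by 2.41 (SE 0.17) and Cd74, the invariant chain, by 1.66 (SE 0.16). Macrophage markers rose beside both lists, with a median of 1.54. Of the antigen presentation genes 3 rose without HACY replicate 1 and 6 without HACY replicate 2.

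Acute phase and complement genes had 18 rises and no fall among 21 (19 rises when adjusted over the list alone; median 1.31), beside secreted hepatocyte proteins, which share no member and had a median of 1.30. Without CCL4 replicate 1 there were 15 rises and 1 fall, that of Socs3, named after its values were seen (-0.56, adjusted p = 0.0485; -0.25 with all libraries, adjusted p = 0.510). Hc, complement component C5, rose by 2.62 (SE 0.18) and Itih4 by 1.61 (SE 0.12). Camera gave adjusted p = 5.25e-11 (adjusted p = 0.415 with an estimated correlation). Inflammatory cytokines and NF-kappaB targets had 5 rises and 1 fall among 19 (8 and 2 when adjusted over the list alone; median 0.48; camera adjusted p = 0.0910). Cxcl10, an interferon-induced chemokine, rose by 2.29 (SE 0.27) and Il1a by 1.82 (SE 0.22), and Icam1, an adhesion molecule, had -0.99 (SE 0.18), a call lost without HACY replicate 2 (adjusted p = 0.0550). There were 2 rises without HACY replicate 1 (median 0.24), and 7 rises and 3 falls without CCL4 replicate 2, and the list passed camera's threshold without HACY replicate 2 (adjusted p = 0.0122) and by library size alone.

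Markers of other liver cells moved unevenly. Kupffer cell and macrophage markers had 15 rises and no fall among 19 (16 rises when adjusted over the list alone; median 1.54; camera adjusted p = 1.54e-09; adjusted p = 0.415 with an estimated correlation). Adgre1, the F4/80 antigen, went from 20.8 ± 2.62 to 112 ± 26.3 CPM and Marco, a scavenger receptor, from 97.4 ± 10.4 to 353 ± 69.5 (SD, n = 2). Endothelial markers had 5 rises and 1 fall among 17 (12 and 1 when adjusted over the list alone; median 0.83; camera adjusted p = 8.70e-04; adjusted p = 0.658 with an estimated correlation). Lyve1 rose by 2.90 (SE 0.39) and Clec4g, of sinusoidal endothelium, had -1.87 (SE 0.48). Stellate cell markers had 1 rise among 13, Ecm1 (0.85, SE 0.15), and 1 when adjusted over the list alone (median 0.24; camera adjusted p = 0.302). Endothelial rises numbered 1 without HACY replicate 1, 2 without CCL4 replicate 1 (median 0.47) and 12 without CCL4 replicate 2 (median 1.38), where 4 stellate markers rose and the stellate list passed camera's threshold (median 0.64), as it did without HACY replicate 1 (0.38). The Clec4g call was lost without HACY replicate 1, HACY replicate 2 or CCL4 replicate 2 (adjusted p = 0.235, 0.208 and 0.102), and the Ecm1 call without HACY replicate 2 (0.0713), where the stellate median was 0.13, and 2 stellate markers fell without CCL4 replicate 1 (median 0.053).

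Blood cell markers differed by type. Of 17 neutrophil genes 1 rose and 3 fell (2 and 8 when adjusted over the list alone; median -0.96; camera adjusted p = 0.302). Cxcr2, a chemokine receptor, had -3.34 (SE 0.76) and Lcn2, also an acute phase gene, 1.09 (SE 0.26). CCL4 replicate 2 stood apart: S100a8 and S100a9, abundant neutrophil transcripts named after their values were seen, had 51.8 and 112 CPM there, against 5.51 and 11.8 in CCL4 replicate 1 and at most 3.06 and 6.75 in HACY. Without CCL4 replicate 1, 12 neutrophil genes fell, none rose and the list passed camera's threshold (median -3.23), and without CCL4 replicate 2, 6 rose and 2 fell and the median turned positive (0.54). Without HACY replicate 1 there was 1 rise and no fall, and without HACY replicate 2 neither (medians -2.35 and -2.27). The Lcn2 call was lost without HACY replicate 2 (0.65, adjusted p = 0.108) or CCL4 replicate 1 (0.121), and that of Cxcr2 without HACY replicate 1 or HACY replicate 2 (0.246 and 0.247), with a value of -1.83 without CCL4 replicate 2. B cell markers had 6 rises and no fall among 17 (7 rises when adjusted over the list alone; median 0.45; camera adjusted p = 0.00557; adjusted p = 0.506 with an estimated correlation). The B cell median was 0.72 without HACY replicate 2, 0.75 without CCL4 replicate 1 and 0.83 without CCL4 replicate 2. Those that rose included Cd74 and Cd72 (2.38, SE 0.28), and Cd79b, of the B cell receptor, had -0.43 (SE 0.34, adjusted p = 0.448). Several B cell members, Cd74 among them, are also made by macrophages and dendritic cells.

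Dendritic cell markers had 3 rises among 11 (5 when adjusted over the list alone; median 0.74; camera adjusted p = 0.00373; adjusted p = 0.506 with an estimated correlation), with Itgax at 1.84 (SE 0.29). There was 1 rise without HACY replicate 1 or CCL4 replicate 1. Plasma cell genes had 1 rise among 8, Jchain (1.12, SE 0.25; 2 rises when adjusted over the list alone; median 0.56; camera adjusted p = 0.0439; adjusted p = 0.588 with an estimated correlation). The plasma cell call was lost without HACY replicate 2, without CCL4 replicate 1 and after correction for GC content and length, and Jchain was lost after that correction (adjusted p = 0.0603) and without HACY replicate 1 (0.185), HACY replicate 2 (0.0719) or CCL4 replicate 1 (0.0560), and 3 plasma cell genes rose without CCL4 replicate 2 (median 0.92, and 0.24 without CCL4 replicate 1). Only 4 T and NK cell genes were tested, too few for camera, and Ccl5 (1.99, SE 0.23) and Gzmb (7.97-fold, log2 SE 0.70) rose (3 rises when adjusted over the list alone); Gzmb was lost without HACY replicate 2 (log2 2.47, adjusted p = 0.198) or CCL4 replicate 2 (2.32, 0.0604), and it had 4.28 without CCL4 replicate 1, on 8 and 2 counts in the CCL4 libraries. No erythroid gene of 6 passed edgeR's or DESeq2's threshold, or that adjusted over the list alone, and 3 were higher at an unadjusted p below 0.05 (median 0.86; camera adjusted p = 0.0270; adjusted p = 0.415 with an estimated correlation). That list's call was lost without HACY replicate 2 (0.0772) or CCL4 replicate 2 (0.0536), where 1 member rose.

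**Figure D3:**
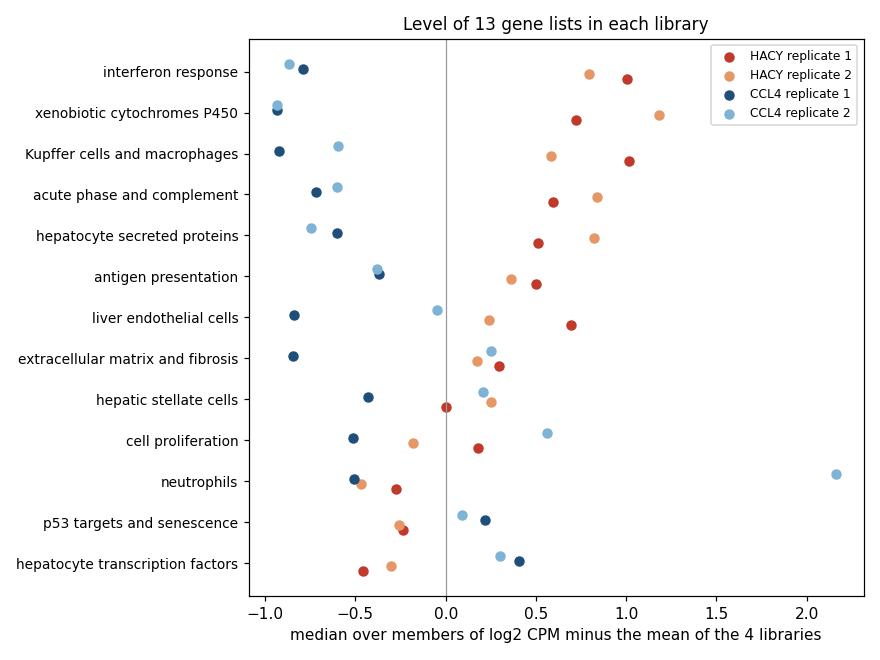
Median over members of log2 CPM minus the mean of the 4 libraries, for 13 gene lists in each library. Interferon genes lie at 1.00 and 0.79 in HACY and at -0.79 and -0.87 in CCL4, while neutrophil markers lie at 2.16 in CCL4 replicate 2 and at -0.51 in CCL4 replicate 1.

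Targets of p53 and senescence genes were lower in HACY. Of 18 tested, 5 fell and none rose (9 fell when adjusted over the list alone; median -0.48; camera adjusted p = 0.00320; adjusted p = 0.415 with an estimated correlation). Phlda3, an inhibitor of AKT, had -1.03 (SE 0.13) and Gdf15, a stress cytokine, -1.25 (SE 0.20). There were 2 falls without HACY replicate 1 or HACY replicate 2. Oxidative stress and NRF2 targets had 4 rises and 1 fall among 19 (7 and 1 when adjusted over the list alone; median 0.14; camera adjusted p = 0.237). The NRF2 median was 0.016 without HACY replicate 1, 0.37 without HACY replicate 2, -0.0014 without CCL4 replicate 1 and 0.30 without CCL4 replicate 2. Gstm1 rose by 1.68 (SE 0.19) together with Gstm3, and Slc7a11, the cystine transporter, had -1.34 (SE 0.14). Hspa5 (0.57, SE 0.13) and Hsp90b1 (0.57, SE 0.14), chaperones of the endoplasmic reticulum, were the rises among 15 ER stress genes (3 when adjusted over the list alone; camera adjusted p = 0.772). Both were lost without HACY replicate 1, HACY replicate 2 or CCL4 replicate 1 (adjusted p = 0.0643 to 0.281), by library size alone and after correction for GC content and length, and 5 genes of the list rose without CCL4 replicate 2.

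Early genes that dissociation can induce had 3 rises and 1 fall among 21 (5 and 4 when adjusted over the list alone; camera adjusted p = 0.885), but 1 rise and 4 falls by library size alone. Dusp1, a phosphatase, rose by 1.18 (SE 0.14) and Zfp36, which destabilises mRNA, by 0.69 (SE 0.15), and there was 1 rise without HACY replicate 1 and 3 falls without CCL4 replicate 1. The Zfp36 call was lost without HACY replicate 1 or HACY replicate 2 (adjusted p = 0.218 and 0.0579), and 2 genes fell without CCL4 replicate 2. No proliferation gene of 25 passed edgeR's threshold or that adjusted over the list alone, 2 were higher at an unadjusted p below 0.05, and DESeq2 called 1 (median -0.08; camera adjusted p = 0.756, direction up). Without CCL4 replicate 2, 8 proliferation genes rose (median 0.51), and without CCL4 replicate 1, 4 fell (-0.55); camera called the list in each case, in opposite directions, and the median was -0.29 without HACY replicate 1 and 0.058 without HACY replicate 2. Sex-biased liver genes had 3 rises among 7 (4 when adjusted over the list alone; median 1.54; camera adjusted p = 0.0114; adjusted p = 0.415 with an estimated correlation), including Cyp2a4 (2.67, SE 0.46) and Cyp2b9 (1.52, SE 0.32), and the list's call was lost without CCL4 replicate 2 (0.0889) and that of Cyp2b9 without HACY replicate 1 (0.184). That sex-biased list was not split by the sex in which a gene is higher, so its direction tells nothing about sex. It shares Cyp2d9 with the cytochrome P450 list. No sex-linked transcript was tested. Ddx3y and Uty had 0 counts in all 4 libraries, Eif2s3y 1 count in each HACY library and Kdm5d 1 count in HACY replicate 1.

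Over the 37 lists, 35 were tested by camera and 19 were called, 17 higher and 2 lower. With an estimated correlation none was called, with 1 list at an unadjusted p below 0.05. The p53 list's unadjusted camera p went from 8.22e-04 to 0.0686, although its estimated correlation of -0.019 lay below the preset 0.01. The loss of calls therefore does not measure correlation between genes alone. By fry, which tests whether a list's genes move one way on balance, none was called either (smallest adjusted p = 0.0569; 10 lists at an unadjusted p below 0.05), and 25 were called for change in either direction. The median and mean differed in sign for the fetal liver, lipid synthesis and early gene lists, and the median and camera's direction for proliferation. By library size alone the medians of the bile acid, TGF-beta, glycolysis, NRF2 and ER stress lists turned negative, and after correction for GC content and length that of ER stress turned negative and those of the NOTCH and early gene lists positive. On the log2(FPKM + 1) scale, which understates changes of low genes, the calls of Slc6a19, Il1f9, Mmp9, Anxa4, Cd44, Ptprb, Lcn2, Cyp4a10, Zfp36, Hspa5 and Hsp90b1 ended. Besides that of Mmp9, limma-voom ended the calls of Slc6a19, Il1f9, Cyp27b1, Tbx3, Junb, Clec4g, Cxcr2 and Cyp4a10, and the absence of a filter those of Serpina1e, Cyp27b1, Lcn2 and Cxcr2. The Clec4g call also ended by DESeq2 and with the stricter filter, and those of Lcn2, Hspa5 and Hsp90b1 with upper-quartile scaling. By DESeq2 the rises numbered 8 in the actin list, 11 in the endothelial, 7 in the NRF2, 5 in the dendritic, 4 in the biliary and 3 in the matrix list, 2 in the stellate, plasma cell and glycolysis lists and 1 in the NOTCH list, and 3 early genes and no endothelial marker fell. By limma-voom 3 p53 targets fell, no neutrophil, Wnt, TGF-beta, endothelial or early gene fell, and no fatty acid oxidation gene rose. By library size alone 9 p53 targets fell, 1 periportal gene fell, the Wnt list had 1 rise and 2 falls, the biliary list 1 and 2, the NRF2 list 3 and 2, and the ER stress list no rise and 1 fall. After correction for GC content and length 7 TGF-beta targets, 6 actin, 2 matrix, 2 glycolysis and 1 NOTCH gene rose, no TGF-beta target fell, early genes had 4 rises and no fall, and the ER stress and plasma cell lists had neither rise nor fall by edgeR.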

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

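The weighing tests in this part were chosen after the results were seen, as was the comparison of FPKM with counts. After a first run, the tests on GC content and length were given bootstrap intervals in place of fixed limits, and the test of hepatocyte RNA share for the transcription factors was replaced by a comparison with biliary markers, and no reading changed. When these tests were then required to hold without each library, both explanations of the transcription factors' fall were left open. In 80 genes the deposited FPKM was above 0 although no library had a count, and 13 of these had an FPKM of at least 1 in all 4 libraries. These values lie in a column that the main test does not use. Both HACY values lay above both CCL4 values in 3 of the 13 genes and below them in 4, where chance gives 2.17 in each direction. Apoc4-apoc2, a readthrough of neighbouring apolipoprotein genes, had a mean FPKM of 89.2 in HACY and 37.0 in CCL4. Gm21975 had 8.07 and 3.12, and Gm21949 had 6.45 and 3.96. The other way, Clk2-scamp3 had a mean FPKM of 8.42 in HACY and 10.6 in CCL4, Gm38495 7.67 and 8.47, Snurf 5.44 and 7.37, and Gm20604 3.54 and 6.47. The differences were not tested, and the counts of genes are close to chance.

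Hepatocyte transcription factors fell (6 of 17, but 2 without HACY replicate 1 and 3 without HACY replicate 2) while secreted hepatocyte products rose (13 of 19), list calls lost with an estimated correlation (adjusted p = 0.415 each) and by fry (0.0931 and 0.0569). A bias from GC content and transcript length cannot be told apart for the factors: after each library's trends were removed their median was -0.61 (95% bootstrap interval over members -1.09 to -0.02), but without HACY replicate 1 the interval was -1.01 to 0.14. A larger share of hepatocyte RNA would raise these factors, or lower them together with markers of displaced cells, and cannot be told apart either: their median lay -1.25 from that of the biliary and progenitor markers (interval -1.65 to -0.29), but -0.58 without CCL4 replicate 1 (-1.24 to 0.076), where the biliary median was 0.013 instead of 0.45, and -1.04 without HACY replicate 1 (-1.60 to 0.0083). For the products that share cannot be told apart from regulation: 6 of 19 had a 95% interval below the list median, none fell, and levels per cell type were not analysed here. The treatment itself also stays open as an untested explanation.

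Of macrophage markers 15 of 19 rose, as did 16 of 17 interferon response genes, list calls lost with an estimated correlation (adjusted p = 0.415 each) and by fry (0.0697 and 0.0569). A lower share of the main cell type would raise all other types alike. Which type is the main one was not established here. The labels describe hepatocytes, whose secreted products rose (median 1.30) while hepatocyte transcription factors fell (median -0.80). The macrophage median exceeded the stellate median by 1.30, and by 0.95 to 1.59 with each library left out, over 2 bootstrap standard errors each time. These errors treat markers as independent and are too small, as the estimated correlation was 0.78 in the stellate list and 0.29 in the macrophage list. Stellate markers also differed by a median of 1.06 between the CCL4 libraries, so a lower share is not excluded. A larger share of macrophages carrying the interferon genes cannot be told apart from a response in other cells, since the interferon median exceeded the macrophage median by 0.23 with an interval of -0.22 to 0.58 (by 0.38 without HACY replicate 1 and 0.027 without CCL4 replicate 2). The sort for CD24 would remove macrophages that lack it, yet the most abundant markers of the list, Gpnmb and Cd5l, had 1191 and 788 CPM in HACY and 452 and 256 in CCL4. The treatment stays open as well.

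Several clock genes were lower in HACY libraries. Of 16 clock genes listed after several had been seen among the falls, 7 fell and none rose, with a median of -0.85; 4 fell without HACY replicate 1, 2 without HACY replicate 2, 5 without CCL4 replicate 1 and 10 without CCL4 replicate 2. Another time of day at collection cannot be told apart from an effect of treatment. The labels give no time of collection, and none of the genes that peak opposite to the Per genes passed the threshold. Arntl had 0.30 (edgeR adjusted p = 0.362), Npas2 -0.79 (0.166) and Clock -0.19 (0.417). The fall was not shared by all the listed genes. Nr1d2 had -0.32 (edgeR adjusted p = 0.390), Bhlhe41 -0.018 (0.971) and Dbp 0.087 (0.865). After the trends on GC content and length were removed, the median was -0.73 instead of -0.85 (95% bootstrap interval -1.07 to -0.39). It was -0.46 without CCL4 replicate 1 (-0.66 to -0.15), the smallest of the 4 such fits. Most of the listed genes' median thus remained. The interval treats the genes as independent and is too narrow. Because the genes were listed after falls had been seen, it cannot exclude GC content and length as a cause. With all 4 libraries and these trends removed, 5 fell: Hlf was gained (-1.34, edgeR adjusted p = 0.0387) and Per1, Per2 and Nr1d1 were lost. The changes of the 3 lost genes shrank and their errors grew, from -0.87 (SE 0.17), -0.94 (SE 0.23) and -1.36 (SE 0.31) to -0.64 (SE 0.21), -0.89 (SE 0.25) and -1.28 (SE 0.36).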

How the results depend on the processing

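Alternatives on the FPKM column, on GC content and length, and on list members without each library were chosen after seeing the data. No gene called in the main test changed sign under any setting in which it was tested. The number of calls ranged from 629 to 3047 with each library left out, those higher from 530 to 1840 and those lower from 99 to 1207; the lone library of a group is then assumed to vary like the other group's pair. A 2-fold requirement left 928 calls, 696 higher and 232 lower. Lower calls numbered 1355 by library size alone, 738 by DESeq2 and 728 with GC content and length offsets, and higher calls 670 with FPKM; the cause was not tested. Of the 1576 calls, 602 were kept without HACY replicate 1, 735 without HACY replicate 2, 1099 without CCL4 replicate 1 and 1496 without CCL4 replicate 2. Cd24a ranged from -0.88 to -0.0033 with each library left out. Col3a1, at -0.12 with all libraries (edgeR adjusted p = 0.918), ranged from -0.84 (0.0134) without CCL4 replicate 1 to 1.40 (0.00391) without CCL4 replicate 2. Between the same fits the matrix list's median ranged from 0.039 (camera's direction down) to 1.07 and the proliferation list's from -0.55 to 0.51. The cause of these was not tested. List calls fell from 19 to 0 with an estimated correlation and to 0 by fry. The mean r within groups exceeded that between groups by 0.0304, and by 0.0130 with no filter, which adds genes of few counts. With the replicate block 1224 genes were called and 1159 of the main calls kept, and all 19 list calls were kept, while among named genes Mmp9, Abcc2, Tbx3, Junb, Ptprb, Clec4g, Jchain, Gzmb, Cyp4a10, Hspa5 and Hsp90b1 were lost. Replicate numbers gave a correlation of -0.0989 between the groups' deviations across genes over 2 pairs. That is too few pairs to show or exclude a shared batch or pairing. The removal of haemoglobin, immunoglobulin and mitochondrial genes took out 1 tested gene, and the share without mitochondrial genes was not run because no row carried that prefix. Small changes were often missed on simulated counts, where 12.2% of 1.5-fold changes were found. Depth and the number of libraries were not varied there. The simulation changed 200 genes, against 1576 called in the data, so recovery in the data may differ.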

Other observations

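Gene families, defined after the results were seen as symbol stems with at least 10 tested members, added groups that the lists do not hold. Of 159 stems, tested for enrichment among rises and falls by one-sided Fisher tests with adjustment over 318 tests, 12 were enriched among the rises and 2 among the falls. Carboxylesterase genes (Ces) had 9 rises and no fall among 12 (median log2 fold change 1.47, adjusted p = 1.80e-06), and glucuronosyltransferases (Ugt) 9 and none among 14 (1.77, 1.17e-05). Toll-like receptors (Tlr) had 7 rises among 10 (1.26, 9.30e-05). The Ces and Ugt families hold near-identical paralogs, so their counts are uncertain, and members of a family are not independent.

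Zinc finger genes named Zfp had 40 falls and 2 rises among 334 (median -0.44, adjusted p = 1.35e-09 for falls). After offsets for GC content and length there were 64 falls and 3 rises, with a median of -0.46. Kelch-like genes (Klhl) had 5 falls and no rise among 26 (-0.31, adjusted p = 0.0442). Genes of autophagy picked after their values were seen included Sqstm1, a cargo receptor, with 1848 CPM in HACY and 3018 in CCL4 (log2 -0.71, SE 0.15, edgeR adjusted p = 0.0272), and Map1lc3a (-1.19, SE 0.22, 0.0185), while the Atg stem had 3 falls among 18 and was not enriched (adjusted p = 0.407).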
